A study of Mus musculus with 56 samples.

How the data were processed

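Monocytes and macrophages sorted from injured tissue gave 56 libraries, with 1 injury per mouse per the series text. Libraries were 3′ libraries with unique molecular identifiers (UMIs), per the labels' protocols. Whether UMIs were collapsed, which annotation was used and the versions of the authors' tools are not given in the sources used here. The heart table holds whole-number counts per gene, made with STAR, Salmon, featureCounts and limma on GRCm38, per the submitters' processing notes. The bone, muscle and skin table holds estimated counts that the authors deposited, made with STAR, featureCounts and limma per the same notes, which list both GRCm38 and GRCm39. Of its non-zero values 19.4 percent lay over 0.01 from a whole number, and all were rounded before the test. Both tables are unscaled. They hold 52636 and 57010 genes, of which 52403 and 52029 identifiers matched a table of gene names. Coordinates are from GENCODE mouse release 21 (GRCm38).

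Groups follow the labels, which give bone days 7 and 10 although the series text names days 4 and 7. Heart columns carry no replicate number of the labels. They were assigned to groups by name, and those that name no day were taken as day 7 because the day 4 columns say so. They are called here by their own names. The labels do not say that libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be in part technical. Genotype and depletion go together. Replicates of a group differed beyond counting noise (chi-square per degree of freedom from 5.47 to 28.8), so none was counted as a copy of another.

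Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr, robust quasi-likelihood fits and Benjamini-Hochberg adjustment, with a threshold of 0.05. The 4 groups of a tissue shared a fit, and bone, muscle and skin shared a fit of 12 groups for differences between tissues. Heart, in another table, was left out of those. The SE is the absolute log2 change over the square root of F. Genes tested numbered 11339 in heart, 12709 in bone, 12907 in muscle and 12616 in skin. 8 depletion comparisons were made, each with control libraries of its own. 30 gene lists were tested with camera of limma 3.58.1 (correlation 0.01, prior count 2), with an estimated correlation and with fry, adjusted over all lists and comparisons. A gene was said to have copies, and marked with a dagger, where at least 0.05 of its 31-base words occur in another annotated gene. This rule was chosen after the data were seen. Antisense and overlapping genes were not set apart.

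Alternatives were RLE normalization, no filter on low counts, DESeq2 1.42.0, limma-voom, a fit of the compared groups alone, the replicate number as a block and each library left out. Design, gene lists, these alternatives and the rule for named genes were fixed before the data were examined. The rule takes called genes with at least 5 CPM in one group, no overlap and a gene symbol: the 8 largest changes per direction (4 in other comparisons) and up to 3 members per list, besides a fixed panel, genes shared by 3 or more tissues and genes of the closing section. In heart it was also applied to genes without copies, after the data were seen. From this set the genes printed were picked after their values were seen, mainly those whose calls held with each library left out. Of 699 called values in the set, 498 held so and 201 did not, so the printed genes are no random draw from it.

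The fits were tested on simulated counts with 200 changed genes. In the order heart days 4 and 7, bone days 7 and 10, muscle days 4 and 7 and skin days 4 and 7, 72, 80, 74, 47, 66, 66, 58 and 65 percent of genes changed 2-fold were found and 94, 97, 99, 90, 98, 95, 100 and 97 percent of those changed 4-fold, with 3, 6, 10, 6, 13, 7, 5 and 8 false calls.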

Results

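Monocytes and macrophages were sorted from injured heart (myocardial infarction), bone (a defect in the skull), muscle (a defect that removes a volume of muscle) or skin (a punch wound), and their RNA was sequenced in bulk from the 3′ ends of transcripts. All mice received diphtheria toxin. In Foxp3-DTR/GFP mice the toxin receptor is expressed from the Foxp3 locus, so that the toxin removes regulatory T cells (Tregs), and cells from these mice are called depleted. Cells from toxin-treated wild-type C57BL/6J mice, which keep their Tregs, are the controls. The 56 libraries fell into 16 groups. Heart and muscle gave 3 depleted and 3 control libraries at days 4 and 7 after injury, skin gave 4 and 4 at the same days, and bone gave 5 and 5 at day 7 and 3 and 3 at day 10. Total counts per library were 2642452 to 9788811 in heart, 2318268 to 5835113 in bone, 3439692 to 6397434 in muscle and 3013776 to 5392932 in skin. Values are mean ± SD in CPM (counts scaled to library size), depleted against control, and each log2 change has its standard error (SE). Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists from limma's camera. A dagger (†) marks a gene with copies by the shared-word rule, whose counts are uncertain because reads may have been divided among genes.

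Foxp3, the gene that carries the toxin receptor, was looked at first (ENSMUSG00000039521, GRCm38 chromosome X, 7573644 to 7595245). It had no counts in any of the 12 heart libraries. In bone it had 22 counts over the 5 control libraries of day 7 (1.69 ± 2.43 CPM) and 7 over the 5 depleted libraries (0.275 ± 0.31), and at day 10 3 in each arm. Skin had 28 control counts at day 7 (1.60 ± 0.971 CPM) and 3 depleted counts (0.246 ± 0.493), and 6 and 1 at day 4. Muscle had 0 control and 2 depleted counts at day 4 and 4 and 1 at day 7. Foxp3 was too low for a test in all 4 tissues, and because the sorted cells are not T cells its level does not check the labels.

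**Figure D1:**
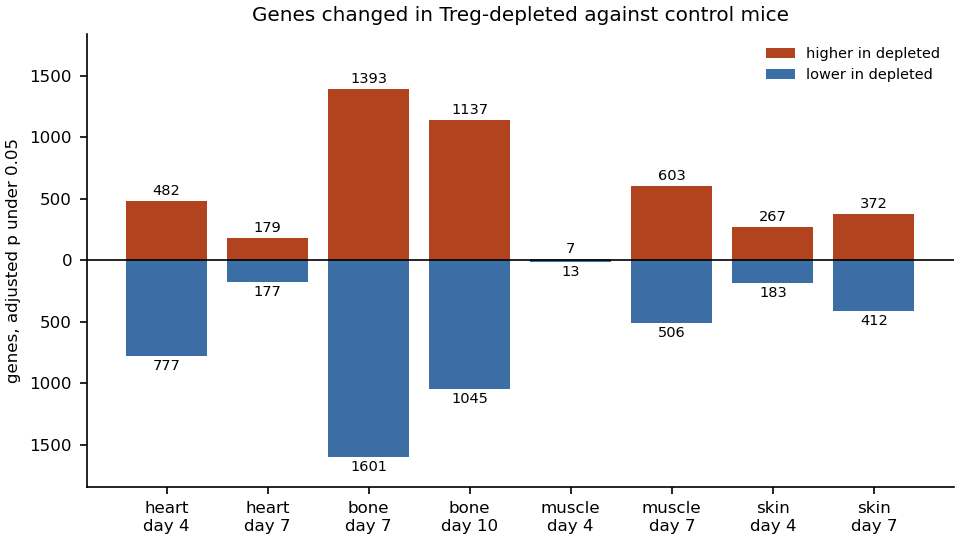
Number of genes with an adjusted p under 0.05 (edgeR quasi-likelihood test) in each of the 8 comparisons of depleted with control cells, with genes higher in depleted cells as bars above 0 and genes lower as bars below 0. Bone day 7 has 1393 higher and 1601 lower genes, and muscle day 4 has 7 and 13.

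In the infarcted heart at day 4, genes of the interferon response were higher in depleted cells (n = 3 per group). Among them were Psmb8 (1606 ± 496 against 674 ± 72.1 CPM, log2 change 1.25, SE 0.20, adjusted p = 0.000637) and Psmb9 (354 ± 137 against 138 ± 15.6 CPM, log2 change 1.36, SE 0.26, adjusted p = 0.00673), which encode subunits of the immunoproteasome. Of 42 interferon response genes, 14 rose, 0 fell and 28 did not pass. 28 rose and 0 fell adjusted over the list alone (median log2 change 1.19, camera adjusted p = 1.5e-12, adjusted p = 0.402 with an estimated correlation). Depleted F3 stood apart, with Gbp2 at 1122 CPM against 116 in F1 and 157 in F2. The list had 12 rises without F3 (median 0.66, camera adjusted p = 7.3e-11), 24 without F2, and 6, 8 and 4 without control W1, W3 and W4. The monocyte surface marker Ly6c2† (log2 change 1.83, adjusted p = 0.00691) and Ide, which encodes the insulin-degrading enzyme (69.9 ± 6.70 against 34.8 ± 4.14 CPM, log2 change 1.01, SE 0.14, adjusted p = 4.87e-05), also rose. Genes of resident macrophages were lower, among them Lyve1 (3.94 ± 1.39 against 12 ± 4.00 CPM, log2 change -1.71, SE 0.37, adjusted p = 0.00593), a hyaluronan receptor, and Cbr2† (log2 change -1.08, adjusted p = 0.00614). Among 23 resident macrophage genes, 0 rose and 6 fell, while 17 did not pass. 0 and 9 did so adjusted over the list alone (median log2 change -0.41, camera adjusted p = 0.00536, adjusted p = 0.554 with an estimated correlation, and adjusted p = 0.0757 and a median of -0.25 without depleted F3). The scavenger receptor gene Stab1 (178 ± 33.9 against 337 ± 18.3 CPM, log2 change -0.92, SE 0.14, adjusted p = 0.000111) and the transcription factor gene Cebpb (log2 change -1.61, adjusted p = 0.000962) fell as well. T and NK cell markers had 4 of 12 members higher, 0 lower and 8 not passing. 6 rose and 0 fell adjusted over the list alone (median log2 change 2.11, camera adjusted p = 0.00215, adjusted p = 0.377 with an estimated correlation, and a median of 1.35 without depleted F3). For neutrophil markers, 0 of 16 rose, 3 fell and 13 did not pass. 0 and 3 did so adjusted over the list alone (median log2 change -0.23, camera adjusted p = 0.0314, adjusted p = 0.489 with an estimated correlation, adjusted p = 0.0502 to 0.0667 without any of depleted F2 and F3 and control W4, and a median of -0.15 without depleted F3). The neutrophil granule gene Ltf (log2 change -3.48, adjusted p = 0.00056) fell.

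Of the 137 genes that fell at least 4-fold at heart day 4, 104 have copies or no known share of words. So have 20 of the 37 that rose as much and 18.4 percent of all genes tested. Rps12† was at 3.42 ± 0.642 against 1561 ± 184 CPM (log2 change -8.77, SE 0.18, adjusted p = 9.22e-18), Gapdh† at 3.03 ± 2.35 against 210 ± 5.11 CPM and Rps6† at 1.75 ± 0.583 against 358 ± 53.3 CPM. Ribosomal protein genes together held 26700 CPM in depleted and 70590 CPM in control libraries (exact permutation p = 0.1, two-sided, the smallest 3 against 3 allows), and at day 7 26020 and 24310. In all, 1259 of 11339 genes passed, 482 higher and 777 lower, and without the genes with copies, an alternative chosen after the data were seen, 560 passed, 231 higher and 329 lower. The count was 780 without depleted F3, and 839 and 686 without control W1 and W4.

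**Figure D2:**
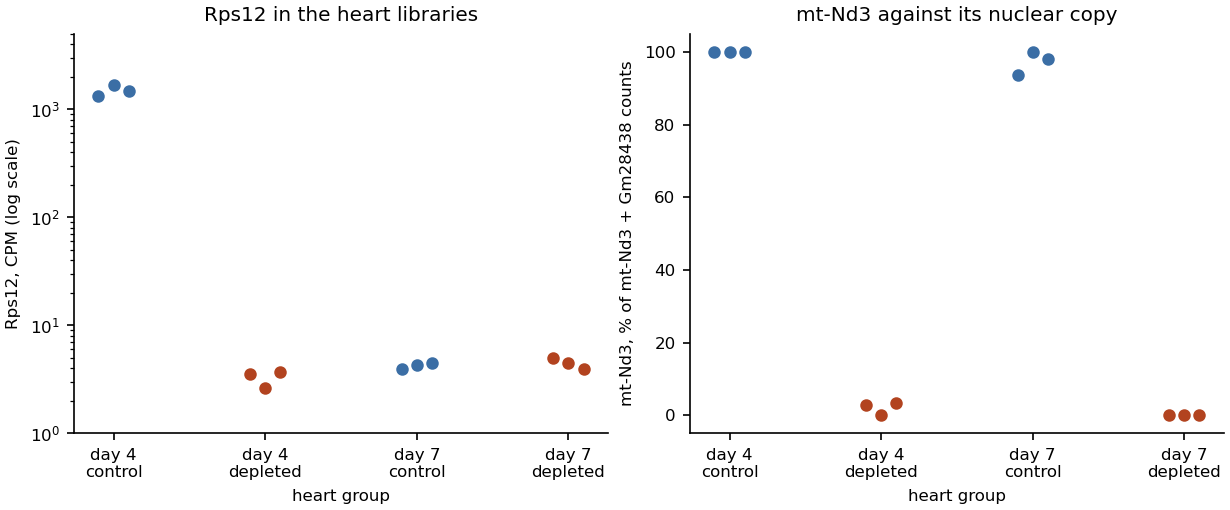
Left, Rps12 in CPM (log axis) in each of the 12 heart libraries. Right, counts of mt-Nd3 as a percentage of the counts of mt-Nd3 and its nuclear copy Gm28438 together in the same libraries. Rps12 is at 1340 to 1687 CPM in the day 4 controls and at 2.65 to 5.03 CPM in the other 9 libraries, and mt-Nd3 makes up 93.6 to 100 percent of both genes in controls and 0 to 3.45 percent in depleted libraries.

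At day 7 after infarction, Lyve1 (6.36 ± 1.78 against 26.0 ± 9.08 CPM, log2 change -2.04, SE 0.31, adjusted p = 0.00188), Folr2 (109 ± 15.0 against 207 ± 11.3 CPM, log2 change -0.92, SE 0.16, adjusted p = 0.0053), which encodes folate receptor beta, and Hpgd (22.8 ± 4.98 against 104 ± 27.9 CPM, log2 change -2.18, SE 0.29, adjusted p = 0.00247), which encodes a prostaglandin-degrading enzyme, fell in depleted cells (n = 3 per group). For resident macrophage genes, 0 of 23 rose, 4 fell and 19 did not pass. 0 and 7 did so adjusted over the list alone (median log2 change -0.35, camera adjusted p = 4.05e-05, adjusted p = 0.402 with an estimated correlation). Chitinase-like Chil3† (log2 change 2.40, adjusted p = 0.0053), the myeloid inhibitory receptor Cd300lf (207 ± 36.4 against 91.5 ± 2.06 CPM, log2 change 1.18, SE 0.16, adjusted p = 0.00143) and the sialic acid-binding receptor of eosinophils Siglecf (log2 change 2.14, adjusted p = 0.00668) rose. Of 3 mast cell, basophil and eosinophil markers, 2 rose, 0 fell and 1 did not pass. 2 rose and 0 fell adjusted over the list alone (median log2 change 2.14, camera adjusted p = 0.000758, adjusted p = 0.22 with an estimated correlation). Among 16 neutrophil markers, 4 rose and 0 fell, while 12 did not pass. 7 and 0 did so adjusted over the list alone (median log2 change 0.87, camera adjusted p = 1.01e-06, adjusted p = 0.229 with an estimated correlation, and a median of 0.39 and 1.39 without depleted FDG2 and control WT3 in turn). Interferon response genes had 2 of 42 members higher, 3 lower and 37 not passing. 15 rose and 7 fell adjusted over the list alone (median log2 change 0.64, camera adjusted p = 0.0168, adjusted p = 0.79 with an estimated correlation, adjusted p = 0.0547 to 0.321 without any of depleted FDG1 and FDG2 and control WT3, and a median of 0.42 without depleted FDG1). The antiviral gene Rsad2 (log2 change -1.19, adjusted p = 0.00825) fell.

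The early response genes Fos (log2 change -0.85, adjusted p = 0.00362) and Zfp36 (log2 change -0.67, adjusted p = 0.00525), which cell isolation can induce, fell. Of 22 dissociation stress and early response genes, 0 rose, 7 fell and 15 did not pass. 0 rose and 9 fell adjusted over the list alone (median log2 change -0.38, camera adjusted p = 3.44e-06, adjusted p = 0.377 with an estimated correlation, and a median of -0.18 without control WT3). Among 31 oxidative phosphorylation genes, 1 rose and 0 fell, while 30 did not pass. 3 and 0 did so adjusted over the list alone (median log2 change 0.19, camera adjusted p = 4.75e-06, adjusted p = 0.363 with an estimated correlation). Mitochondrial transcripts held 19520 CPM in depleted and 23330 CPM in control libraries (exact permutation p = 0.1, two-sided). In all, 356 of 11339 genes passed, 179 higher and 177 lower. This count was 615 by DESeq2, 599 by limma-voom and 754 with no filter on low counts. It was 166 and 218 without depleted FDG1 and FDG2, and 184, 172 and 124 without control WT1, WT3 and WT4.

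In bone at day 7, genes of tissue macrophages were lower and genes of dividing cells higher in depleted cells (n = 5 per group). Cx3cr1 (38.3 ± 10.3 against 217 ± 36.7 CPM, log2 change -2.51, SE 0.18, adjusted p = 2.92e-08), the fractalkine receptor, Apoe (991 ± 305 against 6824 ± 1279 CPM, log2 change -2.78, SE 0.22, adjusted p = 1.27e-07), a lipid-carrying apolipoprotein, C1qa (58.5 ± 21.8 against 285 ± 28.8 CPM, log2 change -2.28, SE 0.29, adjusted p = 2.99e-05), a complement component, and Folr2 (13.9 ± 9.50 against 116 ± 27.5 CPM, log2 change -3.06, SE 0.35, adjusted p = 1.27e-05) fell. Of 23 resident macrophage genes, 0 rose, 19 fell and 4 did not pass. 0 rose and 19 fell adjusted over the list alone (median log2 change -1.71, camera adjusted p = 3.49e-17, adjusted p = 0.226 with an estimated correlation). Among 24 lipid-associated macrophage genes, such as Trem2 (log2 change -2.12, adjusted p = 4.75e-07), 0 rose and 22 fell, while 2 did not pass. 0 and 23 did so adjusted over the list alone (median log2 change -1.62, camera adjusted p = 6.55e-19, adjusted p = 0.169 with an estimated correlation). Efferocytosis and scavenging genes had 1 of 20 members higher, 14 lower and 5 not passing. 1 rose and 15 fell adjusted over the list alone (median log2 change -1.39, camera adjusted p = 9.89e-08, adjusted p = 0.226 with an estimated correlation). The mitosis genes Top2a (334 ± 34.4 against 101 ± 27.9 CPM, log2 change 1.72, SE 0.16, adjusted p = 4.75e-07) and Nusap1 (243 ± 20.4 against 86.9 ± 8.83 CPM, log2 change 1.48, SE 0.14, adjusted p = 3.91e-07) rose. For cell cycle genes, 31 of 31 rose, 0 fell and 0 did not pass. 31 and 0 did so adjusted over the list alone (median log2 change 1.16, camera adjusted p = 9.11e-21, adjusted p = 0.229 with an estimated correlation). Psmb9 (log2 change 1.74, adjusted p = 6.41e-08) and the peptide transporter gene Tap1 (log2 change 1.44, adjusted p = 5.32e-07) rose. Among 41 interferon response genes, 19 rose and 7 fell, while 15 did not pass. 19 and 7 did so adjusted over the list alone (median log2 change 0.56, camera adjusted p = 0.000875, adjusted p = 0.638 with an estimated correlation). Depleted replicate 3 stood apart, with Gbp2 at 259.6 CPM against 40.4 to 109 in the other depleted libraries, and without it the list's median was 0.37 (camera adjusted p = 0.00993).

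Markers of other cells moved at the same time in depleted bone at day 7. The neutrophil collagenase gene Mmp8 (log2 change 1.30, adjusted p = 7.21e-06) and Lcn2 (log2 change 1.54, adjusted p = 0.000188), which encodes a neutrophil iron-binding protein, rose. Of 18 neutrophil markers, 8 rose, 0 fell and 10 did not pass. 12 rose and 1 fell adjusted over the list alone (median log2 change 0.97, camera adjusted p = 0.000376, adjusted p = 0.443 with an estimated correlation). Granzyme B gene Gzmb (log2 change 3.74, adjusted p = 2.82e-05) and the mast cell protease gene Cpa3 (log2 change 3.03, adjusted p = 0.000748) rose. Among 16 T and NK cell markers, 11 rose and 1 fell, while 4 did not pass. 11 and 2 did so adjusted over the list alone (median log2 change 2.11, camera adjusted p = 0.000728, adjusted p = 0.434 with an estimated correlation). Mast cell, basophil and eosinophil markers had 6 of 13 members higher, 0 lower and 7 not passing. 6 rose and 0 fell adjusted over the list alone (median log2 change 0.88, camera adjusted p = 0.00115, adjusted p = 0.443 with an estimated correlation, and a median of 0.57 and 1.55 without depleted 2 and control 2 in turn). For fibroblast and mural cell markers, 0 of 17 rose, 5 fell and 12 did not pass. 0 and 14 did so adjusted over the list alone (median log2 change -1.65, camera adjusted p = 1.32e-05, adjusted p = 0.489 with an estimated correlation). Of 10 dendritic cell markers, 0 rose, 6 fell and 4 did not pass. 0 rose and 6 fell adjusted over the list alone (median log2 change -0.74, camera adjusted p = 0.000439, adjusted p = 0.332 with an estimated correlation). The immediate early gene Egr1 (log2 change -1.84, adjusted p = 2.83e-06) and the phosphatase gene Dusp1 (log2 change -2.11, adjusted p = 4.75e-07) fell. Of 22 dissociation stress and early response genes, 0 rose, 16 fell and 6 did not pass. 0 rose and 17 fell adjusted over the list alone (median log2 change -0.97, camera adjusted p = 4.54e-09, adjusted p = 0.29 with an estimated correlation).

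In all, 2994 of 12709 genes passed in bone at day 7, 1393 higher and 1601 lower. Rn18s-rs5, a ribosomal RNA gene that priming at poly(A) tails should mostly leave out, stood at 73300 ± 22520 against 34450 ± 25370 CPM (exact permutation p = 0.0397, two-sided, smallest possible 0.00794). With its log2 CPM as a covariate, chosen after the data were seen, 1166 genes passed, 487 higher and 679 lower, and with replicates 1 to 3 of each arm 1986 passed.

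**Figure D3:**
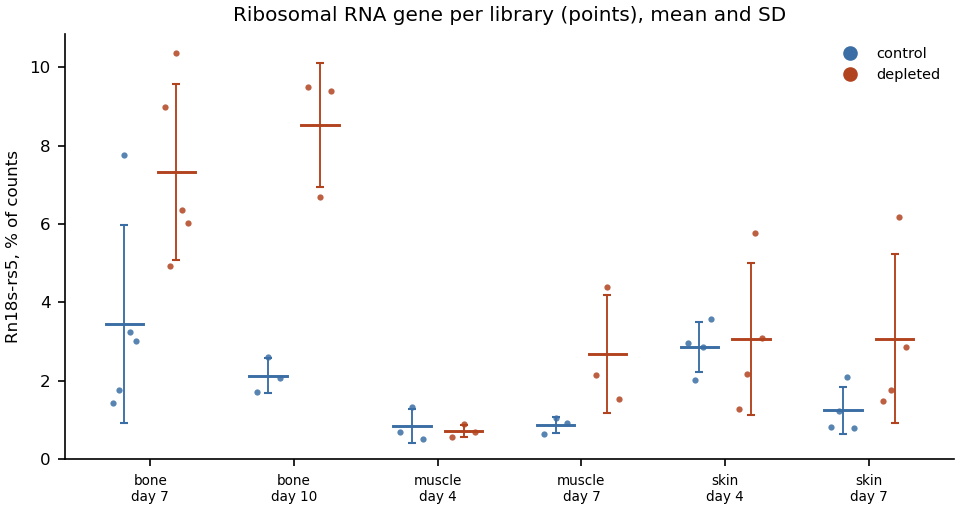
Counts of Rn18s-rs5 as a percentage of all counts in each bone, muscle and skin library, with the mean and SD of each group. In bone at day 7, 1 control library, replicate 3, lies at 77600 CPM and the other 4 controls at 14200 to 32500 CPM.

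In bone at day 10, macrophage genes were lower and cell cycle genes higher in depleted cells (n = 3 per group). Cx3cr1 (21.7 ± 4.14 against 109 ± 13.4 CPM, log2 change -2.32, SE 0.24, adjusted p = 9.98e-06), Apoe (1120 ± 371 against 4165 ± 855 CPM, log2 change -1.89, SE 0.27, adjusted p = 0.000251) and the lectin gene Cd209a (6.71 ± 2.44 against 84.2 ± 24.2 CPM, log2 change -3.64, SE 0.33, adjusted p = 1.56e-06) fell. Resident macrophage genes had 0 of 23 members higher, 11 lower and 12 not passing. 0 rose and 14 fell adjusted over the list alone (median log2 change -1.07, camera adjusted p = 5.47e-06, adjusted p = 0.434 with an estimated correlation). For lipid-associated macrophage genes, 0 of 24 rose, 15 fell and 9 did not pass. 0 and 17 did so adjusted over the list alone (median log2 change -1, camera adjusted p = 7.82e-09, adjusted p = 0.341 with an estimated correlation). Il6 (46.1 ± 5.54 against 8.69 ± 4.10 CPM, log2 change 2.36, SE 0.33, adjusted p = 0.000131), Nusap1 (log2 change 1.51, adjusted p = 3.89e-05), Mmp8 (log2 change 1.88, adjusted p = 2.61e-05) and Psmb9 (log2 change 1.49, adjusted p = 4.08e-05) rose. Of 31 cell cycle genes, 20 rose, 0 fell and 11 did not pass. 24 rose and 0 fell adjusted over the list alone (median log2 change 0.83, camera adjusted p = 6.44e-12, adjusted p = 0.341 with an estimated correlation). Among 18 neutrophil markers, 11 rose and 0 fell, while 7 did not pass. 13 and 1 did so adjusted over the list alone (median log2 change 1.57, camera adjusted p = 2.97e-05, adjusted p = 0.394 with an estimated correlation). Osteoclast markers had 0 of 11 members higher, 7 lower and 4 not passing. 0 rose and 9 fell adjusted over the list alone (median log2 change -1.22, camera adjusted p = 7.3e-06, adjusted p = 0.341 with an estimated correlation). Il4, a type 2 cytokine gene, was at 13.1 ± 2.84 against 0.537 ± 0.234 CPM (log2 change 4.45, SE 0.79, adjusted p = 0.000873).

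Of 12 mitochondrial transcripts, 10 rose, 0 fell and 2 did not pass. 11 rose and 0 fell adjusted over the list alone (median log2 change 1.17, camera adjusted p = 2.38e-07, adjusted p = 0.332 with an estimated correlation). Interferon response genes had 6 rises and 12 falls among 41 members (12 and 13 adjusted over the list alone), a median of -0.04, a mean of 0.06 and a test direction of down (camera adjusted p = 0.958, adjusted p = 0.984 with an estimated correlation). Mitochondrial transcripts held 24850 against 12480 CPM (exact permutation p = 0.1, two-sided), and Rn18s-rs5 was at 85310 ± 15890 against 21280 ± 4540 CPM (exact permutation p = 0.1, two-sided). In all, 2182 of 12709 genes passed, 1137 higher and 1045 lower, and with the Rn18s-rs5 covariate 78 passed, 26 higher and 52 lower. Of the 101 values of named genes, 81 no longer passed with it. The count was 1181 and 1244 without depleted replicates 1 and 3, and 1430 and 1279 without control replicates 2 and 3.

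Muscle at day 4 showed few changes of single genes (n = 3 per group). The heat shock genes Hspa1a† (16.5 ± 1.27 against 93.7 ± 18.9 CPM, log2 change -2.51, SE 0.17, adjusted p = 1.73e-07) and Hspa1b† (2.05 ± 0.702 against 15.3 ± 1.65 CPM, log2 change -2.89, SE 0.34, adjusted p = 0.000616) fell in depleted cells. Among 22 dissociation stress and early response genes, 0 rose and 2 fell, while 20 did not pass. 0 and 10 did so adjusted over the list alone (median log2 change -0.41, camera adjusted p = 1.5e-12, adjusted p = 0.165 with an estimated correlation). Interferon response genes had 0 of 42 members higher, 0 lower and 42 not passing. 17 rose and 1 fell adjusted over the list alone (median log2 change 0.47, camera adjusted p = 3.85e-06, adjusted p = 0.528 with an estimated correlation). Depleted replicate 1 stood apart, with Gbp2 at 212 CPM against 44.8 and 86.2 in replicates 2 and 3, and without it the list's median was 0.15 (camera adjusted p = 0.00218). 6 genes then rose adjusted over the list alone, and 8 without control replicate 1. 20 of 12907 genes passed, 7 higher and 13 lower, against 1089 at an unadjusted p under 0.05. DESeq2 called 87 genes and the test without a filter on low counts 190. The count was 4 and 2 without depleted replicates 1 and 3, and 3, 10 and 8 without control replicates 1, 2 and 3.

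By day 7 in muscle, genes of alternatively activated macrophages and of granulocytes were higher in depleted cells (n = 3 per group). Arg1 (773 ± 57.8 against 38.8 ± 14.0 CPM, log2 change 4.30, SE 0.54, adjusted p = 0.000789), which encodes arginase 1, Ccl24 (641 ± 192 against 69.8 ± 13.9 CPM, log2 change 3.20, SE 0.23, adjusted p = 1.88e-07), which encodes the eosinophil attractant eotaxin-2, and Chil3† (log2 change 5.22, adjusted p = 4.78e-09) rose. Among 28 alternatively activated and repair genes, 15 rose and 5 fell, while 8 did not pass. 15 and 6 did so adjusted over the list alone (median log2 change 0.76, camera adjusted p = 0.00171, adjusted p = 0.165 with an estimated correlation). Prg2 (177 ± 60.02 against 2.6 ± 1.32 CPM, log2 change 6.14, SE 0.34, adjusted p = 4.78e-09), which encodes the major basic protein of eosinophils, and Siglecf (log2 change 3.72, adjusted p = 3.46e-06) rose. Mast cell, basophil and eosinophil markers had 4 of 6 members higher, 0 lower and 2 not passing. 5 rose and 0 fell adjusted over the list alone (median log2 change 3.26, camera adjusted p = 2.93e-07, adjusted p = 0.165 with an estimated correlation). For neutrophil markers, 9 of 14 rose, 0 fell and 5 did not pass. 9 and 0 did so adjusted over the list alone (median log2 change 1.62, camera adjusted p = 2.25e-08, adjusted p = 0.22 with an estimated correlation). Of 17 glycolysis genes, 14 rose, 0 fell and 3 did not pass. 15 rose and 1 fell adjusted over the list alone (median log2 change 0.82, camera adjusted p = 2.1e-11, adjusted p = 0.29 with an estimated correlation). Cx3cr1 (36.8 ± 2.54 against 182 ± 13.8 CPM, log2 change -2.31, SE 0.14, adjusted p = 1.35e-08), Slc40a1 (6.84 ± 1.10 against 49.2 ± 19.0 CPM, log2 change -2.83, SE 0.32, adjusted p = 3.03e-05), the iron exporter, and Gas6 (log2 change -1.99, adjusted p = 1.11e-05), a ligand that bridges dying cells to phagocytes, fell. Among 23 resident macrophage genes, 0 rose and 7 fell, while 16 did not pass. 0 and 11 did so adjusted over the list alone (median log2 change -0.50, camera adjusted p = 3.36e-07, adjusted p = 0.377 with an estimated correlation).

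Matrix remodelling genes, among them Mmp12 (log2 change 1.56, adjusted p = 1.47e-05) and Timp1 (log2 change 2.31, adjusted p = 1.21e-06), had 10 of 27 members higher, 1 lower and 16 not passing. 13 rose and 2 fell adjusted over the list alone (median log2 change 0.41, camera adjusted p = 9.25e-05, adjusted p = 0.169 with an estimated correlation). Of 13 skeletal and cardiac muscle markers, 0 rose, 6 fell and 7 did not pass. 0 rose and 6 fell adjusted over the list alone (median log2 change -1.03, camera adjusted p = 1e-06, adjusted p = 0.29 with an estimated correlation). Interferon response genes moved both ways, with 7 rises such as Tap1 (log2 change 1.08, adjusted p = 0.00275) and 13 falls such as Irf7 (log2 change -1.65, adjusted p = 0.000193) among 42 members (15 and 17 adjusted over the list alone), at a median of 0.17 and a mean of 0.03 while the test direction was down (camera adjusted p = 0.768, adjusted p = 0.984 with an estimated correlation). In all, 1109 of 12907 genes passed, 603 higher and 506 lower. Rn18s-rs5 was at 26890 ± 15030 against 8672 ± 2152 CPM (exact permutation p = 0.1, two-sided), and with it as a covariate 419 genes passed, 239 higher and 180 lower.

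In skin at day 4, interferon-responsive genes were higher and genes of the cell cycle lower in depleted cells (n = 4 per group). Gbp2 (130.2 ± 28.1 against 23.8 ± 3.84 CPM, log2 change 2.46, SE 0.23, adjusted p = 1.23e-06), a guanylate-binding protein gene, Cxcl9 (50.2 ± 24.5 against 4.46 ± 2.40 CPM, log2 change 3.53, SE 0.46, adjusted p = 0.00024), a chemokine that draws T cells, and Irf1 (165 ± 35.1 against 52.6 ± 4.31 CPM, log2 change 1.65, SE 0.17, adjusted p = 3.59e-06), an interferon-induced transcription factor, rose. For interferon response genes, 17 of 42 rose, 1 fell and 24 did not pass. 19 and 4 did so adjusted over the list alone (median log2 change 0.33, camera adjusted p = 6.75e-07, adjusted p = 0.434 with an estimated correlation, and a median of 0.18 and 0.19 without depleted 1 and control 1 in turn). Cenpe (3.06 ± 1.28 against 11.0 ± 3.54 CPM, log2 change -1.84, SE 0.33, adjusted p = 0.0018), a kinetochore motor, and Ccnb1† (log2 change -1.28, adjusted p = 0.00228) fell. Of 31 cell cycle genes, 0 rose, 11 fell and 20 did not pass. 0 rose and 20 fell adjusted over the list alone (median log2 change -1.04, camera adjusted p = 3.49e-17, adjusted p = 0.165 with an estimated correlation). Cx3cr1 (19.4 ± 7.94 against 113 ± 38.4 CPM, log2 change -2.54, SE 0.29, adjusted p = 2.96e-05), Folr2 (log2 change -1.29, adjusted p = 0.00222) and Apoe (log2 change -1.42, adjusted p = 0.00155) fell. Among 23 resident macrophage genes, 0 rose and 11 fell, while 12 did not pass. 0 and 15 did so adjusted over the list alone (median log2 change -0.68, camera adjusted p = 9.59e-10, adjusted p = 0.341 with an estimated correlation). Il6 (142 ± 90.4 against 15.8 ± 5.26 CPM, log2 change 3.15, SE 0.56, adjusted p = 0.00694) rose. Pro-inflammatory mediator genes had 4 of 28 members higher, 0 lower and 24 not passing. 7 rose and 1 fell adjusted over the list alone (median log2 change 0.37, camera adjusted p = 0.000408, adjusted p = 0.44 with an estimated correlation, and a median of 0.22, 0.61 and 0.24 without depleted 2, control 1 and control 4 in turn).

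The basophil protease gene Mcpt8 (329 ± 195 against 3.18 ± 1.59 CPM, log2 change 6.61, SE 0.63, adjusted p = 5.1e-05) rose in skin at day 4. Of 12 mast cell, basophil and eosinophil markers, 4 rose, 0 fell and 8 did not pass. 4 rose and 0 fell adjusted over the list alone (median log2 change 0.79, camera adjusted p = 0.00192, adjusted p = 0.322 with an estimated correlation, and a median of 0.48 without depleted 2). Ccl24 (log2 change 2.12, adjusted p = 0.011) and Ly6c2† (log2 change 1.97, adjusted p = 5.3e-05) rose. Among 25 monocyte genes, 4 rose and 1 fell, while 20 did not pass. 10 and 2 did so adjusted over the list alone (median log2 change 0.42, camera adjusted p = 0.000844, adjusted p = 0.29 with an estimated correlation). Gzmb (log2 change 3.67, adjusted p = 0.0173), a protease gene of cytotoxic lymphocytes, rose, but not by limma-voom or with any of these libraries left out: depleted 4 and control 3 and 4 (log2 3.17 to 3.68). T and NK cell markers had 3 of 11 members higher, 0 lower and 8 not passing. 3 rose and 1 fell adjusted over the list alone (median log2 change 0.82, camera adjusted p = 0.0879, adjusted p = 0.602 with an estimated correlation). In all, 450 of 12616 genes passed, 267 higher and 183 lower. With no filter on low counts 719 passed, and the count was 265 without depleted replicate 4, and 274 and 283 without control replicates 3 and 4.

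At day 7 in skin, Gbp2 (109.5 ± 41.4 against 14.8 ± 1.74 CPM, log2 change 2.88, SE 0.24, adjusted p = 2.22e-07), Cxcl9 (57.0 ± 23.6 against 3.07 ± 1.44 CPM, log2 change 4.16, SE 0.47, adjusted p = 3.46e-05), Tap1 (log2 change 1.41, adjusted p = 4.46e-06) and Psmb9 (log2 change 1.38, adjusted p = 6.39e-05) were higher in depleted cells (n = 4 per group). Of 42 interferon response genes, 20 rose, 2 fell and 20 did not pass. 21 rose and 3 fell adjusted over the list alone (median log2 change 0.84, camera adjusted p = 8.99e-12, adjusted p = 0.341 with an estimated correlation). H2-DMa (779 ± 161 against 369.9 ± 35.3 CPM, log2 change 1.07, SE 0.15, adjusted p = 5.44e-05), which helps load peptides onto MHC class II, rose. Among 15 genes of MHC class II presentation, 5 rose and 1 fell, while 9 did not pass. 7 and 2 did so adjusted over the list alone (median log2 change 0.36, camera adjusted p = 0.00192, adjusted p = 0.377 with an estimated correlation). Ccl17 (702 ± 284 against 68.0 ± 22.5 CPM, log2 change 3.36, SE 0.41, adjusted p = 0.00014), a chemokine for type 2 T cells, Ccl24 (log2 change 4.04, adjusted p = 6.93e-05) and Pdcd1lg2 (53.1 ± 15.6 against 4.55 ± 2.3 CPM, log2 change 3.48, SE 0.35, adjusted p = 1.55e-06), which encodes the checkpoint ligand PD-L2, rose. Alternatively activated and repair genes had 11 of 28 members higher, 4 lower and 13 not passing. 11 rose and 5 fell adjusted over the list alone (median log2 change 0.59, camera adjusted p = 3.24e-05, adjusted p = 0.248 with an estimated correlation). Tnf (49.9 ± 8.78 against 162 ± 24.1 CPM, log2 change -1.70, SE 0.22, adjusted p = 3.19e-05), Il10 (2.76 ± 1.96 against 10.9 ± 2.23 CPM, log2 change -1.91, SE 0.41, adjusted p = 0.00541) and Cx3cr1 (18.9 ± 4.07 against 142 ± 39.4 CPM, log2 change -2.90, SE 0.29, adjusted p = 3.99e-06) fell. For pro-inflammatory mediator genes, 1 of 28 rose, 7 fell and 20 did not pass. 3 and 9 did so adjusted over the list alone (median log2 change -0.44, camera adjusted p = 0.00222, adjusted p = 0.5 with an estimated correlation).

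The basophil protease gene Mcpt8 (log2 change 4.01, adjusted p = 0.00029) rose in depleted skin at day 7, and Cd207 (log2 change -4.09, adjusted p = 6.39e-05), the langerin gene of Langerhans cells, and Ccr3 (log2 change -4.44, adjusted p = 0.0062), an eotaxin receptor gene, fell. Of 12 mast cell, basophil and eosinophil markers, 6 rose, 2 fell and 4 did not pass. 6 rose and 3 fell adjusted over the list alone (median log2 change 1.47, camera adjusted p = 0.016, adjusted p = 0.377 with an estimated correlation). Among 6 keratinocyte markers, 0 rose and 2 fell, while 4 did not pass. 0 and 2 did so adjusted over the list alone (median log2 change -0.84, camera adjusted p = 0.0041, adjusted p = 0.322 with an estimated correlation). Dissociation stress and early response genes, such as Jun (log2 change -1.17, adjusted p = 0.000741), had 0 of 22 members higher, 14 lower and 8 not passing. 1 rose and 16 fell adjusted over the list alone (median log2 change -0.63, camera adjusted p = 4.04e-11, adjusted p = 0.165 with an estimated correlation). In all, 784 of 12616 genes passed, 372 higher and 412 lower, and without depleted replicate 2 514. Rn18s-rs5 was at 30700 ± 21610 against 12390 ± 6057 CPM (exact permutation p = 0.114, two-sided, smallest possible 0.0286).

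**Figure D4:**
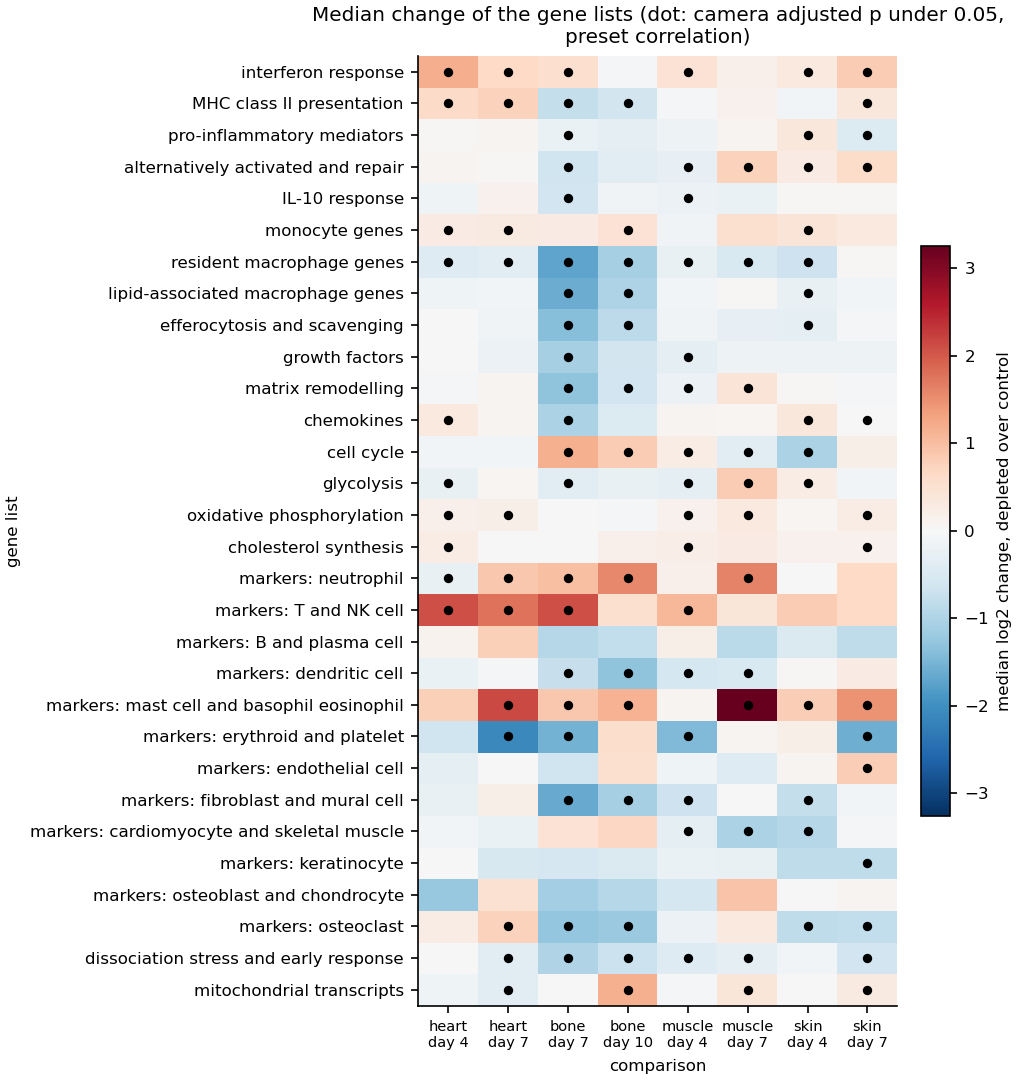
Median log2 change, depleted against control, of the measured members of 30 gene lists in the 8 comparisons, with a dot where camera gave an adjusted p under 0.05 at the preset correlation of 0.01. The cell cycle list has a median of 1.16 in bone at day 7 and -1.04 in skin at day 4.

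**Figure D5:**
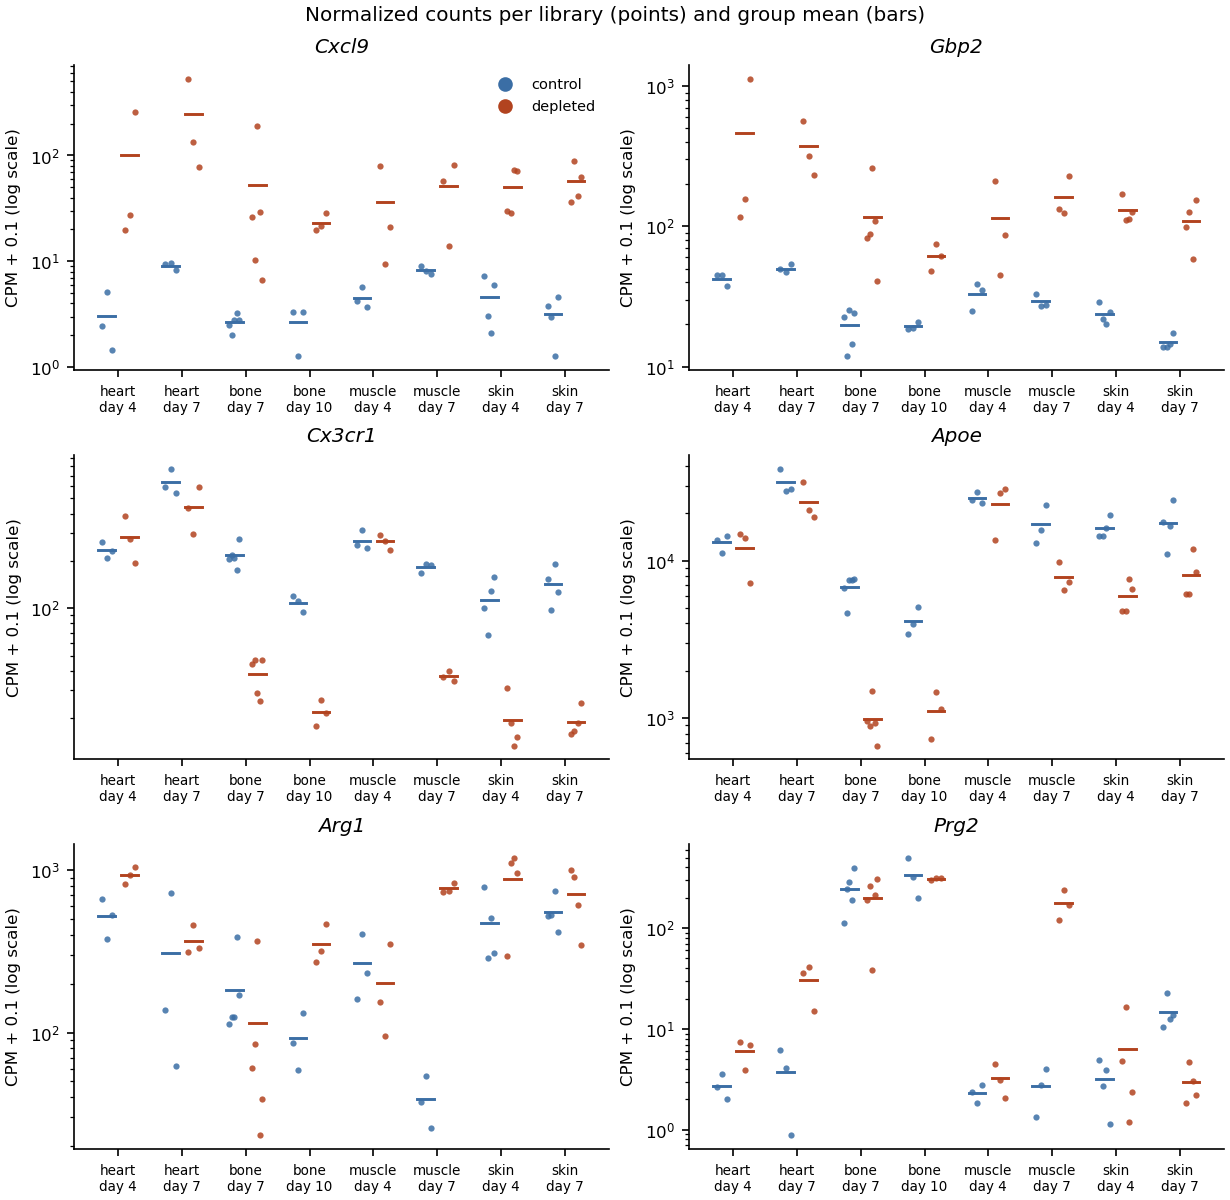
CPM (plus 0.1, log axis) of Cxcl9, Gbp2, Cx3cr1, Apoe, Arg1 and Prg2 in each of the 56 libraries, with a bar at each group's mean. In muscle at day 7 the Arg1 mean is 773 CPM in depleted and 38.8 CPM in control libraries.

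A panel of cytokine and activation genes was followed. Cxcl9, which interferon-γ induces, was higher in every depleted library than in any control library in each of the 8 comparisons, and it passed in skin at day 4 (3.53) and day 7 (4.16) and in bone at day 7 (log2 change 4.36, adjusted p = 0.00424, or a log2 change of 2.83 without depleted replicate 3, and no longer with the Rn18s-rs5 covariate). Its adjusted p was 0.0628 in heart at day 4 and 0.0759 at day 7, 0.109 in bone at day 10, and 0.321 and 0.0791 in muscle. Tnf fell in muscle at day 7 (log2 change -1.16, adjusted p = 0.000366), skin at day 7 (-1.70, adjusted p = 3.19e-05) and bone at day 7 (-1.24, adjusted p = 0.00505, but not with 3 libraries per arm). Il6 passed, higher, in bone at day 10 and skin at day 4, with rises elsewhere left open. Cd274, the gene of the checkpoint ligand PD-L1, rose in muscle at day 7 (1.46, adjusted p = 0.0024) and in skin at day 4 (1.39, adjusted p = 0.00197) and day 7 (1.09, adjusted p = 0.00803). Arg1 passed only in muscle at day 7, with skin day 4 at a log2 change of 0.90 (adjusted p = 0.357) and bone day 10 at 1.94 (adjusted p = 0.156). Ccr2, the chemokine receptor of inflammatory monocytes, and Tgfb1 passed in no comparison, with log2 changes of -0.48 to 0.24 and -0.25 to 0.57. Nos2 was tested only in skin, at 9.43 ± 6.53 against 2.73 ± 2.64 CPM at day 4 (log2 change 1.70, adjusted p = 0.321) and 19.0 ± 11.7 against 13.8 ± 7.23 CPM at day 7 (adjusted p = 0.795).

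Several genes changed the same way in many tissues. 302 genes passed in the same direction in at least 3 tissues and in the other direction in none, 142 higher and 160 lower, and 70 of the 9969 genes tested in all 8 comparisons did so in all 4 tissues. Pls3, an actin-bundling protein gene, was lower in 8 of the 8 comparisons and Pid1 in 7. Psmb9 and Tap1 were higher in 6 each. Not all of these calls held when 1 library was left out. Those of Pls3 ended without any of the following replicates: in bone at day 10 depleted 1, 2 and 3 and control 1 and 2 (log2 -2.06 to -1.38), in muscle at day 4 depleted 1 and 3 and control 2 and 3 (log2 -2.37 to -1.87) and in skin at day 7 depleted 1 and 4 and control 2 (log2 -1.63 to -1.36). For Pid1 they were in heart at day 4 depleted F2 and control W4 (log2 -0.43 to -0.42), in heart at day 7 depleted FDG1, FDG2 and FDG3 and control WT3 and WT4 (log2 -0.51 to -0.41) and in skin at day 4 depleted 4 and control 4 (log2 -0.57 to -0.49). For Tap1 they were in heart at day 4 control W4 (log2 1.70) and in bone at day 10 depleted 2 (log2 0.57). Not all interferon response genes rose like Psmb9 and Tap1, since Ifit3b† was lower in 6 comparisons and Rsad2 in 5, and neither was higher in any. Overlaps of the calls exceeded those of independent lists, for example in muscle at day 7 and skin at day 4 (119 higher against 11.3 and 75 lower against 7.25, each with the number independent lists would share). A one-sided Fisher exact test, adjusted over all pairs of comparisons and both directions, passed except for 4 overlaps with muscle at day 4 and that of lower genes between heart at day 4 and skin at day 7 (adjusted p = 0.0651 to 0.217). These comparisons share no control libraries.

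The next comparisons asked whether the difference between depleted and control cells itself differed between days. In heart, Ltf (log2 0.92 at day 7 against -3.48 at day 4, difference 4.41, SE 0.76, adjusted p = 0.00111) and Fkbp5 (log2 2.50 at day 7 against -1.38 at day 4, difference 3.88, SE 0.56, adjusted p = 0.00111), a glucocorticoid-induced gene, had a higher depletion effect at day 7, and the ribonuclease gene Rnase2a† (log2 0.34 at day 7 against 4.11 at day 4, difference -3.77, SE 0.52, adjusted p = 9.04e-05) a lower one. The lists that passed included interferon response genes (0 up and 6 down of 42, median log2 difference -0.73, camera adjusted p = 1.04e-05, adjusted p = 0.661 with an estimated correlation, and adjusted p = 0.198 and a median of -0.23 without day 4 depleted F3) and neutrophil markers (4 up and 0 down of 16, median log2 difference 1.07, camera adjusted p = 4.64e-07, adjusted p = 0.181 with an estimated correlation, and a median of 0.62 without day 7 depleted FDG2). In all, 464 genes passed, 364 with a higher and 100 with a lower effect at day 7, and without the genes with copies 97, 74 and 23.

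In muscle, Prg2 (log2 6.14 at day 7 against 0.46 at day 4, difference 5.67, SE 0.60, adjusted p = 6.13e-05) had a higher depletion effect at day 7. Alternatively activated and repair genes (10 up and 1 down of 28, median log2 difference 0.66, camera adjusted p = 3.38e-06, adjusted p = 0.0383 with an estimated correlation, and a median of 1.04 without day 4 depleted 1) and glycolysis genes (13 up and 0 down of 17, median log2 difference 1.14, camera adjusted p = 7.72e-17, adjusted p = 0.151 with an estimated correlation) had higher effects at day 7. 311 genes passed, 205 with a higher and 106 with a lower effect at day 7, against 497 by DESeq2, 207 by limma-voom, 583 with no filter on low counts and 69 with the Rn18s-rs5 covariate. The count was 197 and 191 without day 4 depleted replicates 2 and 3, 198 and 167 without day 4 control replicates 1 and 2, and 172 and 154 without day 7 control replicates 2 and 3.

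In skin, P2rx1 (log2 -2.96 at day 7 against 1.42 at day 4, difference -4.37, SE 0.70, adjusted p = 0.00424), an ATP-gated channel gene, and the cytoskeletal gene Septin1 (log2 -2.23 at day 7 against 2.04 at day 4, difference -4.27, SE 0.75, adjusted p = 0.00632) had lower effects at day 7, and Rnase2a† (log2 5.36 at day 7 against -0.48 at day 4, difference 5.84, SE 0.71, adjusted p = 0.000252) a higher one. Cell cycle genes (4 up and 0 down of 31, median log2 difference 1.14, camera adjusted p = 4e-16, adjusted p = 0.103 with an estimated correlation) had higher effects at day 7, and pro-inflammatory mediator genes (0 up and 2 down of 28, median log2 difference -1.03, camera adjusted p = 2.21e-09, adjusted p = 0.216 with an estimated correlation) lower ones. 107 genes passed, 33 higher and 74 lower, against 273 by DESeq2 and 319 with no filter on low counts. The count was 69 without day 4 control replicate 3, 162 and 71 without day 7 depleted replicates 3 and 4, and 68 without day 7 control replicate 2.

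Bone was compared between days 10 and 7. The genes with the smallest p were Rbm3† (log2 difference 1.22), Lman1 (-1.03), Ubl3 (1.24) and Ell2 (1.71), each with an adjusted p of 0.0692. The lists resident macrophage genes (0 up and 0 down of 23, median log2 difference 1.00, camera adjusted p = 7.03e-08, adjusted p = 0.388 with an estimated correlation) and interferon response genes (0 up and 0 down of 41, median log2 difference -0.71, camera adjusted p = 9.7e-07, adjusted p = 0.519 with an estimated correlation, and a median of -0.40 without day 7 depleted 3) passed. No gene passed in edgeR, where 1591 had an unadjusted p under 0.05, and limma-voom called 0, DESeq2 223 and edgeR with no filter on low counts 166. The edgeR count was 27 without day 7 depleted replicate 3, 1 without day 7 control replicate 2, 15 without day 10 depleted replicate 2 and 1 without day 10 control replicate 3.

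In control heart at day 7 against day 4, Lcn2 (1.04 ± 0.708 against 11.6 ± 5.43 CPM, log2 change -3.38, SE 0.47, adjusted p = 3.81e-05) fell and Gpr155 (22.5 ± 4.64 against 2.56 ± 1.28 CPM, log2 change 3.10, SE 0.30, adjusted p = 1.76e-07) rose (n = 3 per group). Lists lower at day 7 included neutrophil markers (0 up and 14 down of 16, median log2 difference -2.39, camera adjusted p = 7.91e-09, adjusted p = 0.106 with an estimated correlation) and cell cycle genes (1 up and 21 down of 31, median log2 difference -0.68, camera adjusted p = 2.69e-08, adjusted p = 0.301 with an estimated correlation). 3607 genes passed, 1696 higher and 1911 lower, among them Rps12† (log2 change -8.54). Copies limit this count: 104 of the 137 large falls at heart day 4 fell at least 4-fold here.

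In control muscle, Saa3† (14.9 ± 3.55 against 143 ± 78.1 CPM, log2 change -3.24, SE 0.53, adjusted p = 0.00423), an acute-phase gene, fell from day 4 to day 7, and Ptn (15.7 ± 4.81 against 0.411 ± 0.217 CPM, log2 change 5.12, SE 0.51, adjusted p = 1.04e-05), a growth factor gene, and Gzma (12.9 ± 4.99 against 0.319 ± 0.141 CPM, log2 change 5.30, SE 0.68, adjusted p = 0.000137), a protease of cytotoxic lymphocytes, rose (n = 3 per group). Fibroblast and mural cell markers (13 up and 0 down of 17, median log2 difference 2.32, camera adjusted p = 5.07e-23, adjusted p = 0.0747 with an estimated correlation) and T and NK cell markers (10 up and 0 down of 13, median log2 difference 3.30, camera adjusted p = 2.11e-10, adjusted p = 0.0646 with an estimated correlation) were higher at day 7. 935 genes passed, 580 higher and 355 lower, with 570 and 570 without day 4 control replicates 2 and 3, and 527 without day 7 control replicate 1.

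In control skin, the platelet chemokine gene Ppbp (15.2 ± 1.11 against 65.4 ± 19.1 CPM, log2 change -2.11, SE 0.33, adjusted p = 0.00205) fell and Cd207 (6.32 ± 1.65 against 0.494 ± 0.21 CPM, log2 change 3.67, SE 0.55, adjusted p = 0.00106) rose between days 4 and 7 (n = 4 per group). Interferon response genes (0 up and 8 down of 42, median log2 difference -0.70, camera adjusted p = 2.32e-15, adjusted p = 0.236 with an estimated correlation) were lower at day 7. 286 genes passed, 179 higher and 107 lower, against 454 by DESeq2, 514 with no filter on low counts and 430 in a fit of these groups alone. The count was 190, 112 and 131 without day 4 control replicates 2, 3 and 4, and 187 and 113 without day 7 control replicates 1 and 2.

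In control bone, day 10 against day 7 (n = 3 and 5), the stromelysin gene Mmp3† (28.4 ± 20.5 against 3.66 ± 1.26 CPM, log2 change 2.92, SE 0.46, adjusted p = 0.0214), the heat shock gene Hspa1a† (log2 change 1.70, adjusted p = 0.0214), Gem (log2 change 2.23, adjusted p = 0.0268), Igfbp4† (log2 change 1.36, adjusted p = 0.0456) and Inhba (log2 change 1.29, adjusted p = 0.0456) rose and no gene fell. Fibroblast and mural cell markers (0 up and 0 down of 17, median log2 difference 1.01, camera adjusted p = 9.7e-07, adjusted p = 0.5 with an estimated correlation) were higher at day 10. DESeq2 called 54 genes, limma-voom 9, the test with no filter on low counts 176 and a fit of these groups alone 13. The edgeR count of 5 (1259 at an unadjusted p under 0.05) was 8, 0 and 0 without day 7 control replicates 2, 4 and 5, and 0, 0 and 12 without day 10 control replicates 1, 2 and 3. None of the 5 genes passed in all 8 fits that left out 1 library.

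Depletion effects at day 7 were then compared between tissues. Prg2 (log2 -0.29 in bone against 6.14 in muscle, difference -6.41, SE 0.80, adjusted p = 3.83e-06) had a lower effect in bone and Gzmb (log2 3.74 in bone, too low in muscle for a test of its own, difference 4.18, SE 0.97, adjusted p = 0.0035) a higher one. Cell cycle genes (26 up and 0 down of 31, median log2 difference 1.66, camera adjusted p = 3.2e-28, adjusted p = 0.0383 with an estimated correlation) had higher effects in bone than in muscle, and lipid-associated macrophage genes (0 up and 19 down of 25, median log2 difference -1.65, camera adjusted p = 2.9e-22, adjusted p = 0.0383 with an estimated correlation) lower ones. 1187 genes passed, 443 with a higher and 744 with a lower effect in bone.

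Between bone and skin, Mamdc2 (log2 -2.77 in bone against 1.65 in skin, difference -4.39, SE 0.82, adjusted p = 0.000329) and Tmem26 (log2 -1.79 in bone against 2.18 in skin, difference -3.95, SE 0.52, adjusted p = 2.37e-06) had lower effects in bone. Lipid-associated macrophage genes (0 up and 21 down of 25, median log2 difference -1.62, camera adjusted p = 6.82e-22, adjusted p = 0.0383 with an estimated correlation) and resident macrophage genes (0 up and 21 down of 23, median log2 difference -1.82, camera adjusted p = 3.51e-25, adjusted p = 0.0646 with an estimated correlation) had lower effects in bone. Cell cycle genes (17 up and 0 down of 31, median log2 difference 1.03, camera adjusted p = 2.06e-16, adjusted p = 0.0815 with an estimated correlation) had higher ones. 1344 genes passed, 544 higher and 800 lower in bone, and with replicates 1 to 3 of each bone arm 859 passed. Between muscle and skin, Chp2 (log2 -2.04 in muscle against 1.19 in skin, difference -3.22, SE 0.73, adjusted p = 0.00493) had a lower effect in muscle. Glycolysis genes (7 up and 0 down of 17, median log2 difference 0.91, camera adjusted p = 1.3e-14, adjusted p = 0.0747 with an estimated correlation) had higher effects in muscle. 398 genes passed, 324 higher and 74 lower in muscle, with 629 where no filter on low counts was used and 251 without muscle depleted replicate 2.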

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

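The tests weighed here for heart, for neutrophils and the macrophage share in bone and for mt-Nd3 were chosen only after the result was seen. The test of RNA quality in bone and the library splits were set beforehand.

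Depletion effects that differed between days or tissues were singled out by edgeR's test of the difference. It gave 464 genes between days in heart, 311 in muscle and 107 in skin. At day 7 it gave 1187 genes between bone and muscle, 1344 between bone and skin and 398 between muscle and skin. Log2 differences of single genes between days in heart were -3.77 for Rnase2a†, 3.88 for Fkbp5, 4.41 for Ltf and 7.75 for Rps6†. They reached 8.84 for Rps12†, 9.2 for Ngp and 9.94 for Camp. In muscle they were 5.67 for Prg2 and -2.82 for Hpgd (-3.43 without day 7 depleted replicate 1). In skin they were -4.37 for P2rx1, -4.27 for Septin1 and F5 and 5.84 for Rnase2a†. The call of F5 ended without day 4 depleted 1 or 2 or control 2, 3 or 4. It also ended without day 7 depleted 1, 2 or 4 or any control of that day (log2 -4.41 to -3.67 in all). Between tissues the log2 differences were -6.41 for Prg2 and 4.18 for Gzmb (bone minus muscle), -4.39 for Mamdc2, -3.95 for Tmem26 and -4.12 for Ccl24 (bone minus skin), and -3.22 for Chp2 and -3.09 for Mamdc2 (muscle minus skin). Ccl24 was at -5.13 without bone depleted replicate 3. The call of Mamdc2 between muscle and skin ended without muscle depleted 2 or 3 or control 2. It also ended without skin depleted 4 or control 1 or 2 (log2 -3.09 to -2.71 in all).

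A library far from the others of its group, by Dixon's test, was found in 16 of 268 groups of values from bone at day 7 and skin, where chance alone marks about 1 in 20. In depleted bone at day 7 these were, in CPM against the range of the other libraries, Folr2 in replicate 3 (30.6 against 7.21 to 12), Pls3 in replicate 1 (7.42 against 0.859 to 2.2), Arg1 in replicate 3 (368 against 23.2 to 85.4), Il6 in replicate 3 (9.91 against 18.9 to 21), Cenpe in replicate 4 (66.6 against 45.8 to 51.9) and Cxcl9 in replicate 3 (190 against 6.59 to 29.1). In control bone they were Tnf in replicate 4 (44 against 23.1 to 26.2), Arg1 in replicate 4 (386 against 113 to 171) and Rn18s-rs5 in replicate 3 (77600 against 14200 to 32500). In skin at day 4 they were Cenpe in replicate 1 (4.97 against 2.27 to 2.5) and Ly6c2† in replicate 1 (1550 against 815 to 883) among depleted libraries. Among controls they were H2-DMa in replicate 4 (415 against 282 to 304) and S100a9 in replicate 3 (86.9 against 32.5 to 36). In skin at day 7 they were Cd207 in replicate 2 (0.657 against 0.235 to 0.288) and S100a9 in replicate 1 (440 against 53.2 to 81.2) among depleted libraries and Ccl17 in replicate 2 (102 against 55.4 to 59.2) among controls.

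Of genes with copies, or with no known share of words, 104 were at least 4-fold lower and 20 at least 4-fold higher in depleted than in control heart libraries at day 4. Lower expression of ribosomal protein genes is argued against by the 3 of them with under 0.05 of their 31-base words shared with another gene, whose median log2 change was 0.42 (SD 0.5), while the other 79 had a median of -2.21 (SD 2.36). A candidate explanation, put as a hypothesis, is that reads shared with copies were counted another way in the day 4 control libraries, since across 82 ribosomal protein genes, which are not independent replicates, the change was lower the more words a gene shared (Spearman rho -0.4, permutation p = 4e-04 from 10000 resamples). Day 7 controls, which keep Tregs, argue against Treg loss. 104 of the 137 falls were at least 4-fold lower there than in day 4 controls. Rps12† was at 1340 to 1687 CPM in those and 2.65 to 5.03 in the other 9 libraries.

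In depleted bone at day 7, macrophage genes were lower and neutrophil and cell cycle genes higher. Of 10 lists of other cells at 5 CPM or more, 7 had a median log2 change below -0.5 (fibroblast and mural cell markers -1.65, SD 0.29) and 3 above 0.5 (neutrophil markers 0.97, SD 0.72). They hold no monocyte genes (median 0.26), so a lower share of macrophages stays open. RNA quality, read as the Rn18s-rs5 share, is argued against for resident macrophage genes alone. The slope within groups of 0.07 (SE 0.18) predicts -5.07 percent (SE 12.7) of their difference of -1.89 in mean log2 level. For other genes it stays open, since fewer passed with it as a covariate. Of the 8 neutrophil markers most abundant in controls, 7 had a log2 change of 0.5 or more, but Mmp9 was at -0.84 (adjusted p = 0.0993). Only S100a9 (3524 ± 1316 against 1412 ± 538 CPM) and Ltf (1053 ± 494 against 489.7 ± 139.7) passed. More neutrophils, which the sort should remove, and Treg loss, with which genotype goes together, cannot be told apart for these genes. The markers are those of the pattern, and monocytes also express S100a9.

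In the heart, counts of mt-Nd3 (GRCm38 chromosome M, 9459 to 9806) and of its nuclear copy Gm28438, an unprocessed pseudogene (chromosome 1, 24612775 to 24613119), exchanged places, at 53 and 0 in day 4 controls, 2 and 77 in depleted cells, and 146 and 4 against 0 and 112 at day 7. Counting of both genes another way in some libraries is argued against by the day 7 controls, which had the low Rps12† of the depleted libraries and yet an mt-Nd3 share of at least 93.6 percent, and lower mitochondrial transcription by the other 7 mitochondrial transcripts, with a median log2 change of -0.35 (SD 0.22) at day 7. A mitochondrial variant of Foxp3-DTR/GFP mice may send reads of mt-Nd3 to its copy, which differs over 345 aligned bases only by T3C, counted from the start of mt-Nd3. Arms should then separate in all 8 comparisons, but controls were higher without overlap in 6, and bone arms overlapped (57.8 ± 0.988 against 58.6 ± 1.64 percent at day 7). Shares outside heart, 55.9 to 62.4 percent, are from estimated counts, which can divide shared reads, so the overlap excludes no variant. In heart both genes summed to 4.31 to 5.82 CPM per group, arguing against lower expression by Treg loss.

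Other splits of the libraries, fitted with edgeR, asked whether chance can be excluded. It can for bone at day 7, where 1 of 100 splits, the real one, gave as many genes (2994, highest other 130). It can for skin, where 1 of 35 splits did so at day 4 (450, highest other 2), at day 7 (784, highest other 8) and between control days (286, highest other 1). It can also for differences between days in heart (1 of 40, 464, highest other 313) and skin (1 of 40, 107, highest other 2). The same holds for differences between tissues (1 of 24 each), with 1187, 1344 and 398 genes and highest others of 580, 974 and 168. For control days in bone the share is as low (2 of 56 splits, 5 genes), but 1 other split gave 7 and the count was 0 without any of 4 libraries, so chance stays possible there. Chance also stays possible for differences between days in muscle (3 of 40 splits, 311 genes, highest other 414). In bone the splits decide nothing, as all 40 reach the real count of 0 (highest other 14). There 1591 genes had an unadjusted p under 0.05, with 223 by DESeq2 and 0 by limma-voom. For 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real counts were 1259 and 356 in heart, 2182 in bone at day 10, 20 and 1109 in muscle, and 3607 and 935 between control days in heart and muscle, with a highest other of 0 in each.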

How the results depend on the processing

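Among these tests, those without genes with copies, with the Rn18s-rs5 covariate, with 3 libraries per arm in bone, of lists with 1 library left out and with other tools for the calls shared between tissues were chosen only after the result was seen.

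Of 3949 values of named genes under the alternatives set beforehand, 3800 kept their direction and side of the threshold, 149 no longer passed and 0 changed direction. Of 715 under the added alternatives, 527 kept both and 187 no longer passed. Rn18s-rs5 in bone at day 10 turned to a log2 change of -0.08 with itself as the covariate, by construction. With 1 library left out, 4584 of 5389 values kept both, 805 no longer passed and 0 turned. The counts of passing genes stayed within 1.5 times of the reported ones under normalization by RLE in all comparisons, and under the other alternatives except as follows. Without genes with copies, heart at day 4 had 560 calls and the heart difference between days 97, in part because fewer genes were tested. With no filter on low counts there were 754 in heart at day 7, 190 in muscle and 719 in skin at day 4. That setting gave 166, 583 and 319 for differences between days in bone, muscle and skin, 176 and 514 between control days in bone and skin, and 629 between muscle and skin. DESeq2 gave 615 in heart at day 7 and 87 in muscle at day 4. For differences between days it gave 223, 497 and 273 in bone, muscle and skin, and between control days 54 and 454 in bone and skin. limma-voom gave 599 in heart at day 7, 207 for the muscle difference between days and 9 between control days in bone. A fit of the compared groups alone gave 13 and 430 between control days in bone and skin. With the Rn18s-rs5 covariate there were 1166 and 78 in bone at days 7 and 10, 419 in muscle at day 7 and 69 for the muscle difference between days. With 3 libraries per arm, bone at day 7 had 1986 and bone against skin 859, with fewer libraries fitted. For the other counts the cause was not tested. Of the 232 list tests of depletion effects 113 passed by camera with the preset correlation, 0 with an estimated correlation (30 at an unadjusted p under 0.05) and 75 by fry, 71 of them among the 113. With 1 library left out, 84 of the 113 were always kept and 29 lost at least once, 1 of which turned (cholesterol synthesis genes in muscle at day 4, adjusted p = 0.958 without depleted replicate 1). The monocyte list at heart day 4 was lost with RLE (adjusted p = 0.0597) and without genes with copies (adjusted p = 0.233). The calls shared by 3 or more tissues rose from 302 to 1145 where an unadjusted p under 0.05 counted in the other tissues, a looser rule by construction.

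Leaving out 1 library gave 686 to 1252 calls in heart at day 4, 124 to 362 at day 7, 2309 to 2972 in bone at day 7, 1181 to 2010 at day 10, 2 to 25 in muscle at day 4, 766 to 1129 at day 7, 265 to 451 in skin at day 4 and 514 to 965 at day 7. For differences between days it gave 316 to 457 in heart, 0 to 27 in bone, 154 to 453 in muscle and 68 to 162 in skin. Between control days it gave 2625 to 3022, 0 to 12, 527 to 760 and 112 to 279 in the same order. Between tissues it gave 839 to 1235, 1041 to 1517 and 251 to 457 for bone with muscle, bone with skin and muscle with skin. Replicate numbers in bone, muscle and skin do not pair the libraries, since deviations of same-numbered libraries correlated by -0.134 to 0.195. Every library correlated best with its own number in bone at day 10 alone, a hint from the data and not from the design. With the number as a block the bone difference between days had 36 calls, and the other counts moved by at most 1.5 times (muscle at day 4 30, bone at day 7 3035). With the block all 91 list calls in these tissues were kept and 4 were gained. In heart no paired analysis was possible because the columns carry no replicate number that matches the labels. In simulated data, whose settings differ in depth, spread and number of libraries together, 47 percent of genes changed 2-fold were found at the settings of bone at day 10 (12709 genes) and 80 percent at those of heart at day 7 (11339 genes), and with 4-fold changes 90 and 97 percent.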

Other observations

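The test of the X chromosome was chosen only after the result was seen.

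As a list, markers of red blood cells and platelets were lower in depleted cells by camera in 4 comparisons. In bone at day 7 the platelet genes Pf4 (log2 change -3.32, adjusted p = 0.000333) and Ppbp (log2 change -3.94, adjusted p = 7.14e-05) fell. Erythroid and platelet markers had 1 of 10 members higher, 7 lower and 2 not passing. 1 rose and 8 fell adjusted over the list alone (median log2 change -1.54, camera adjusted p = 0.00266, adjusted p = 0.378 with an estimated correlation). The list was also lower in heart at day 7 (camera adjusted p = 0.000639, adjusted p = 0.402 with an estimated correlation, but adjusted p = 0.356 without genes with copies), in muscle at day 4 (camera adjusted p = 1e-06, adjusted p = 0.165 with an estimated correlation) and in skin at day 7 (camera adjusted p = 0.00586, adjusted p = 0.402 with an estimated correlation). For IL-10 response genes in bone at day 7, 0 of 15 rose, 8 fell and 7 did not pass. 0 and 9 did so adjusted over the list alone (median log2 change -0.62, camera adjusted p = 0.000821, adjusted p = 0.341 with an estimated correlation). Of 21 growth factor genes there, 2 rose, 10 fell and 9 did not pass. 2 rose and 10 fell adjusted over the list alone (median log2 change -1.07, camera adjusted p = 0.00207, adjusted p = 0.377 with an estimated correlation).

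Of 9 B and plasma cell markers in bone at day 7, 0 rose, 1 fell and 8 did not pass. 0 rose and 1 fell adjusted over the list alone (median log2 change -0.92, camera adjusted p = 0.174, adjusted p = 0.675 with an estimated correlation). Of 5 osteoblast and chondrocyte markers there, 0 rose, 2 fell and 3 did not pass. 0 rose and 2 fell adjusted over the list alone (median log2 change -1.12, camera adjusted p = 0.0511, adjusted p = 0.501 with an estimated correlation). Neither list passed by camera where it was run.

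A hypothesis for the genes changed the same way in all 4 tissues is that a variant of the Foxp3-DTR/GFP strain lies near Foxp3 on chromosome X. Of the 70 genes, 3 lie on X (4.29 percent, against 2.86 percent of the other tested genes; one-sided Fisher exact p = 0.326). Of 38 tested genes within 10 Mb of Foxp3 1 is among them. That gene is Rbm3† (chromosome X, 8138975 to 8145880), a cold-inducible RNA-binding protein gene, called as higher in 6 of 8 comparisons. Its call ended in muscle at day 4 without depleted 2 and 3 or control 1, 2 and 3 (log2 0.69 to 0.87), in muscle at day 7 without depleted 1 and 3 or control 1, 2 and 3 (log2 0.40 to 0.54) and in skin at day 4 without depleted 3 and 4 or control 2, 3 and 4 (log2 0.51 to 0.57), each left out by itself. The test leaves the hypothesis open, since a variant could act on 1 gene, and the loss of Tregs was not tested apart from the strain.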
